A study of Mus musculus with 12 samples.

How the data were processed

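Total RNA from 12 mouse hearts, extracted with Trizol and labelled with biotin, was measured on Affymetrix mouse expression arrays. The labels give 4 groups of 3 arrays, described as biological replicates: wild-type sham, wild-type banded, apelin-knockout sham and apelin-knockout banded. Banded hearts came from mice with aortic banding, an operation that narrows the aorta and makes the left ventricle pump against a raised pressure. Sham mice were the operated controls.

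The values deposited by the authors are a linear intensity for each probe set in each array. The software that made them, and their scaling, are not given in the sources used here. Each array's mean, with 2% of the values left out at each end, was 150, so the arrays were taken as already scaled to one another and no further scaling was applied. The table held 45101 probe sets, of which 64 were controls and were left out of all comparisons. The platform annotation assigned 34958 probe sets to 1 gene and 932 to several genes, and did not list 9160. Of the probe sets with 1 gene, 34754 matched a RefSeq mouse gene by its Entrez number, and no symbol changed. Array data have no read depth, so the number of arrays limits the precision.

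Intensities were transformed as log2(value + 16). Each gene was represented by its probe set with the highest mean over the 12 arrays, which gave 18193 genes, and the upper 60% by mean value, 10916 genes, were tested. One linear model with 4 group means was fitted to all 12 arrays in limma (version 3.58.1, R 4.3.3), with eBayes and a variance trend, leaving 8 residual degrees of freedom. The 7 contrasts were banded against sham in wild type, in knockout and averaged over both, knockout against wild type in sham, in banded and averaged over both, and the interaction, which is the knockout banding effect minus the wild-type banding effect. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the tested genes of a contrast. Fold changes are on the log2 scale, with the standard error (SE) from the fit, and group levels are mean intensities with the SD of 3 arrays.

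The contrasts, filter, pseudocount, gene lists, alternatives and rule for named genes were fixed before the data were examined. The rule takes, in each contrast, the 10 genes with the largest rise and the 10 with the largest fall among those that passed and whose arrays do not overlap between the groups compared. Where fewer than 10 passed, it takes all of them and the 5 genes with the smallest p. It adds up to 4 members of each list past the list test, with the smallest p in the direction of the list. Apln, Aplnr, Nppa, Nppb, Acta1, Myh7, Myh6 and Atp2a2 are always included.

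There were 17 pathway lists: hypertrophy and fetal program, sarcomere, calcium handling, ion channels, fatty acid oxidation, electron transport, glycolysis, extracellular matrix, inflammatory mediators, interferon response, unfolded protein response, antioxidant, angiogenesis and hypoxia, immediate-early genes, cell cycle, circadian clock, and apelin, angiotensin and adrenergic signalling. A further 15 lists held markers: atrial cardiomyocytes, endothelium, fibroblasts, smooth muscle and pericytes, macrophages, neutrophils, lymphocytes, mast cells, erythroid cells, adipocytes, skeletal muscle, lung, mesothelium and epicardium, nerve and glia, and sex-linked genes. Of 510 listed genes, 460 matched the table. Lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a kind within a contrast. Camera was repeated with an estimated correlation, and fry was run as a test of whether a list moves one way. Members passing are counted over all tested genes and adjusted over the list alone.

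Apln was also compared by an exact two-sided permutation test. RNA quality was read as the log2 ratio of the 3' to the 5' control probe sets of Gapdh and Actb. The other settings tried were the filter, the pseudocount, quantile and median scaling, eBayes without the trend, array weights, the mean of a gene's probe sets, all single-gene probe sets, fits of only the groups compared, the replicate block, and leaving out each array in turn. After the data were seen, fits were added without the array labelled knockout banded 1, without that array and wild-type banded 3, and with the atrial marker score as a covariate. Also added then were tests of the marker lists, of the probe sets that best separate the genotypes, of the matrix genes not shared with the fibroblast list, and of the 10092 probe sets with several genes or none listed.

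The procedure was tested on simulated data with 10916 genes and the same groups. Of 100 genes changed 2-fold, 90.0 were recovered for banding in knockout, 89.3 for banding in wild type and 69.0 for the interaction, as means of 3 runs, with false calls at 2.94 to 6.40% of calls over the 7 contrasts. The changed genes were drawn at random and each had the same SD in all groups. The shares are therefore averages and need not hold for genes of large spread. A list shifted by 0.7 log2 was called in 20 of 20 runs, and 2 of 320 unchanged lists were called. The simulated genes varied independently of one another. These runs therefore do not show how often camera at the preset correlation calls unchanged lists whose members vary together, as in the real lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.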

Results

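Gene expression was measured in hearts of wild-type mice and mice lacking the apelin gene, with and without pressure overload, to ask how the heart without apelin differs at rest and under load. Apelin, encoded by Apln, is a peptide that acts on the heart and vessels through the receptor encoded by Aplnr. There were 3 arrays in each of 4 groups: wild-type sham, wild-type banded, knockout sham and knockout banded. The arrays were alike in their distributions, with median intensities of 40.3 to 50.4, highest intensities of 10231 to 21832, and 25.8 to 29.8% of probe sets below 16. Correlations between arrays were 0.962 to 0.984 within groups and 0.944 to 0.98 between groups.

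Apln itself was lower in 5 of the 6 knockout arrays than in every wild-type array. Its mean intensity was 290 ± 67.0 in wild-type sham, 227 ± 25.3 in wild-type banded, 86.7 ± 23.8 in knockout sham and 184 ± 77.0 in knockout banded hearts (SD, n = 3). The exception was the array labelled knockout banded 1, at 271, within the wild-type range of 205 to 333, while the other 5 knockout arrays lay at 63.7 to 160. The wild-type mean was 2.38 times that of these 5 arrays. Knockout against wild type differed by -0.96 log2 (exact permutation p = 0.013, 6 against 6 arrays). Within sham hearts the difference was -1.57 (exact p = 0.10, the smallest that 3 against 3 arrays can give), and within banded hearts it was -0.34 (exact p = 0.40). Apln has a single probe set here, and its position relative to the deleted part of the gene is not known. Directions drawn from the knockout banded group therefore include 1 array that goes against its label for this gene.

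Probe sets of Cd99l2, Fundc2 and Rgs5 read lower in the array labelled knockout banded 1 than in every wild-type array. Cd99l2, a cell surface protein gene, read 171 ± 31.9 in wild-type and 39.3 ± 12.4 in knockout arrays (SD, n = 6) at probe set 1456746_a_at, and 23.9 in this array. Fundc2, a mitochondrial protein gene, read 942 ± 205 in wild-type and 367 ± 106 in knockout arrays at probe set 1460434_at, and 425 in this array. Rgs5, a regulator of G-protein signalling found in pericytes, read at least 454 in each wild-type array at probe set 1420940_x_at and 79.0 in this one. These genes were chosen after their values were seen, because their probe sets passed for genotype averaged over surgery when every single-gene probe set was tested, with this array counted as a knockout. Chosen from the other 11 arrays alone, the 3 probe sets were again among the 10 that best separated the genotypes. A Prune2 probe set, 1432198_at, passed too and does not place this array: it read 95.1 there, 98.3 and 99.5 in knockout banded 2 and 3, at least 1178 in knockout sham and at most 82.3 in wild-type arrays. The probe sets of highest mean for the same genes did not pass in that contrast: Cd99l2 0.22 (adjusted p = 0.432), Fundc2 0.09 (adjusted p = 0.622) and Rgs5 -0.33 (adjusted p = 0.333).

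**Figure D1:**
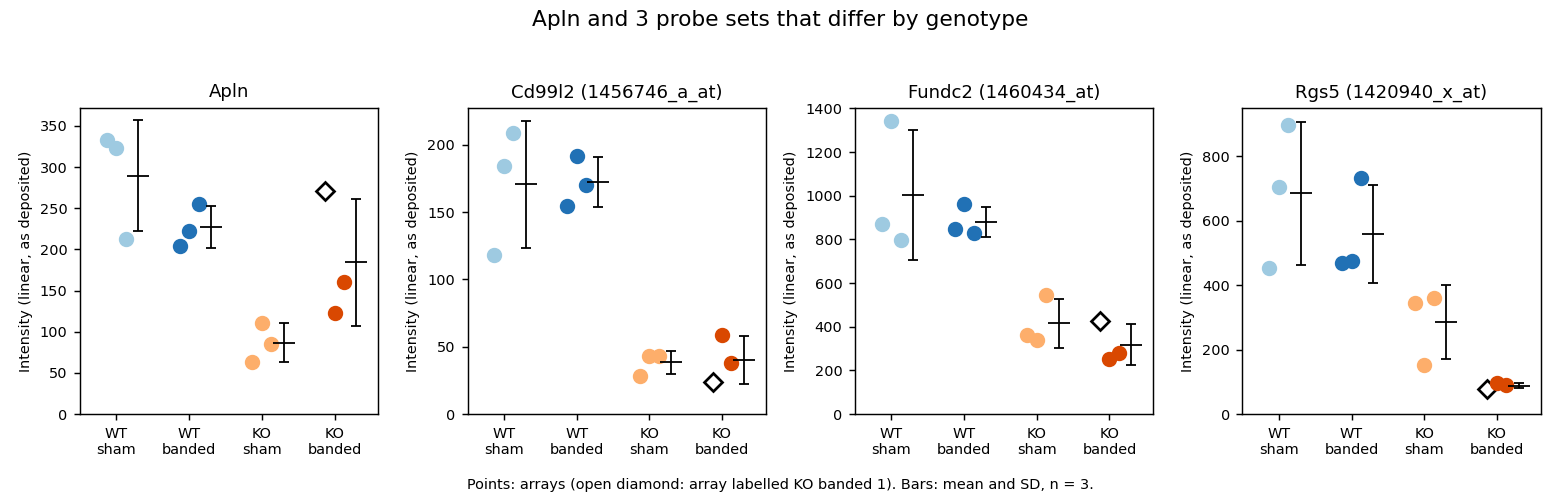
Linear intensity per array (y axis) by group (x axis) for Apln and for probe sets of Cd99l2, Fundc2 and Rgs5, with the mean and SD of 3 arrays beside each group. The array labelled knockout banded 1 (open diamond) is at 271 for Apln, inside the wild-type range, and at 23.9 for Cd99l2, below all 6 wild-type arrays.

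Banding in knockout hearts raised genes of the fetal and hypertrophic program and of the extracellular matrix, and lowered some genes of potassium channels and energy metabolism. Myh7, the slow myosin heavy chain that rises in loaded mouse hearts, went from 1305 ± 303 in sham to 9206 ± 117 in banded hearts (SD, n = 3), a log2 change of 2.83 (SE 0.58, adjusted p = 0.0239). Postn, which encodes the matrix protein periostin, rose by 2.63 (SE 0.54, adjusted p = 0.0241), from 358 ± 5.65 to 3112 ± 2174. The stretch-sensitive regulator Abra rose by 2.27 (SE 0.26, adjusted p = 0.00472), from 197 ± 57.1 to 1026 ± 343. Among the genes that fell were Kcnh2, a cardiac potassium channel, at -1.37 (SE 0.17, adjusted p = 0.00753), and Mylk4, a muscle kinase, at -1.55 (SE 0.21, adjusted p = 0.00848). In all, 416 of 10916 genes passed, 224 higher and 192 lower.

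The other large rises in knockout hearts were Nmrk2 (2.59), Tnfrsf12a (2.58), Ccn2 (2.50), Cilp (2.47), Col8a1 (2.16), Itgbl1 (2.16) and Thbs1 (2.11). The largest falls were Ano10 (-1.86), Ift81 (-1.75), Nup62 (-1.60), Angpt1 (-1.58), Phkg1 (-1.56), Pla2g5 (-1.54), Ppip5k2 (-1.47) and Syt7 (-1.32), with Mylk4 and Kcnh2 above. The value of Nup62 comes from 1 of its 5 probe sets, and the other 4 were at -0.33 to 0.35. The probe sets of lower mean were at -0.43 to -0.09 for Syt7, and the lowest of the 3 of Ift81 was at 0.09. The natriuretic peptide genes, common markers of load, did not pass: Nppb was at 1.42 (SE 0.45, adjusted p = 0.0936) and Nppa at 0.29 (SE 0.48, adjusted p = 0.781). Neither did Myh6, the fast myosin heavy chain, at -0.31 (adjusted p = 0.397), nor the calcium pump gene Atp2a2 at -0.37 (adjusted p = 0.309), nor Aplnr at 0.64 (adjusted p = 0.476). Probe sets of lower mean, not used in this fit, were at -0.78 to -0.26 for Atp2a2 and at -0.53 for Myh6.

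**Figure D2:**
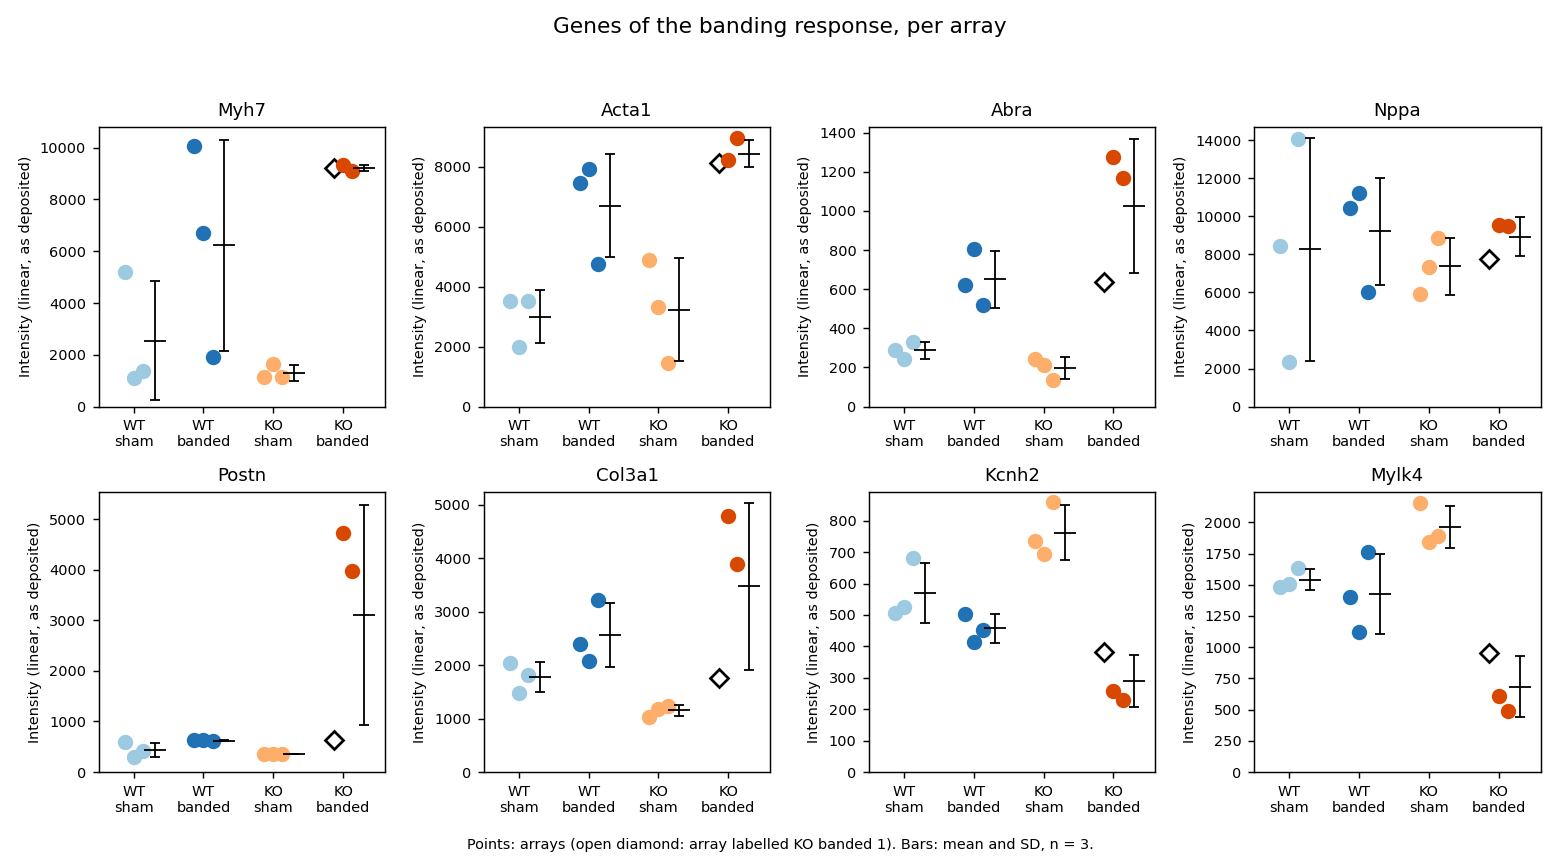
Linear intensity per array (y axis) by group (x axis) for 8 genes of the banding response, with the mean and SD of 3 arrays beside each group. Myh7 is near 9206 in all 3 knockout banded arrays, while Postn is 639 in the array labelled knockout banded 1 (open diamond) against 4719 and 3978 in the other knockout banded arrays.

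By list, the extracellular matrix had the smallest camera p and the most members passing in knockout hearts after banding, while the hypertrophy and fetal program had the larger median. Of its 34 measured members 16 rose, 0 fell and 18 did not pass, 29 were higher adjusted over the list alone, and the median was 1.21. Tgfb2, a growth factor of fibrosis, rose by 1.79, the cross-linking enzyme gene Loxl1 by 1.23 and the collagen gene Col3a1 by 1.47. Camera gave adjusted p = 1.9e-19, and adjusted p = 0.224 with an estimated correlation. In the hypertrophy and fetal program 6 of 13 members rose and 7 did not pass, 10 were higher adjusted over the list alone, and the median was 1.42 (camera adjusted p = 4.7e-10; adjusted p = 0.161 with an estimated correlation). Its members that passed were Myh7, Nmrk2, Fhl1 (1.22), the fast-muscle protein Mybpc2 (2.0), skeletal actin Acta1 (1.54, SE 0.36, adjusted p = 0.0375) and Meox1 (1.80). Of 17 immediate-early genes 1 rose, Klf4 (0.79), 16 did not pass, 1 was higher adjusted over the list alone, and the median was 1.16 (camera adjusted p = 4.0e-06; adjusted p = 0.320 with an estimated correlation). Of 15 inflammatory mediators 0 passed and 3 were higher adjusted over the list alone, with a median of 0.43 (camera adjusted p = 0.0141; adjusted p = 0.366 with an estimated correlation).

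The lists that went down with banding in knockout hearts concern excitation, oxidative metabolism and the circadian clock. Of 16 ion channel genes 3 fell and 13 did not pass, 9 were lower adjusted over the list alone, and the median was -0.59 (camera adjusted p = 1.6e-06; adjusted p = 0.161 with an estimated correlation). The 3 were Kcnh2, Kcnj5 (-1.16) and Abcc9 (-0.69), all genes of potassium channels or their subunits. Of 16 calcium handling genes 2 fell, the channel subunit Cacnb2 (-0.46) and the ryanodine receptor Ryr2 (-0.53), 14 did not pass and 4 were lower adjusted over the list alone (median -0.25, camera adjusted p = 9.4e-04; adjusted p = 0.161 with an estimated correlation). Of 23 fatty acid oxidation genes 1 fell, the thiolase Acaa2 (-1.16), 22 did not pass, and adjusted over the list alone 14 were lower and 1 higher (median -0.46, camera adjusted p = 4.4e-07; adjusted p = 0.320 with an estimated correlation). Of 27 electron transport genes 2 fell, Sdha (-0.47) and Uqcrc2 (-0.39), 25 did not pass, and 2 were lower adjusted over the list alone (median -0.33, camera adjusted p = 1.2e-08; adjusted p = 0.320 with an estimated correlation). Of 14 circadian clock genes 0 passed, and adjusted over the list alone 7 were lower and 1 higher, with a median of -0.74 (camera adjusted p = 0.0201; adjusted p = 0.320 with an estimated correlation). Dbp, a clock output gene, was at -2.10 (adjusted p = 0.114).

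The remaining pathway lists did not pass camera in this contrast: sarcomere (adjusted p = 0.0527), cell cycle (adjusted p = 0.0527), glycolysis (adjusted p = 0.0969), apelin, angiotensin and adrenergic signalling (adjusted p = 0.164), angiogenesis and hypoxia (adjusted p = 0.198), interferon response (adjusted p = 0.198), antioxidant (adjusted p = 0.399) and unfolded protein response (adjusted p = 0.988). Single members of these passed, among them the endothelin receptor gene Ednrb (0.66), the growth factor Vegfc (0.62), the glucose transporter Slc2a4 (-0.68), Sod3 (0.72) and Gstm1 (-0.61). Other measures moved with this comparison. The Actb 3' to 5' log2 ratio was -0.20 ± 0.0231 in knockout banded and 0.15 ± 0.156 in knockout sham arrays (SD, n = 3; exact p = 0.10, the smallest possible). Endothelial markers had a median of 0.20 (camera adjusted p = 0.0348; adjusted p = 0.880 with an estimated correlation). The array labelled knockout banded 1 held airway and fat transcripts, with Scgb1a1 at 1094, Scgb3a2 at 410 and Adipoq at 392. Adipoq was also high in wild-type banded 1, at 327, and at most 103 in the other 10 arrays.

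The count for banding in knockout rests on few arrays. It was 1441 (682 higher, 759 lower) without the array labelled knockout banded 1, with 412 of the 416 genes shared, and 1349 without that array and wild-type banded 3. It was 17 without knockout banded 2, 11 without knockout banded 3, and 88, 40 and 9 without knockout sham 1, 2 and 3. Without the array labelled knockout banded 1, 30 of 34 matrix genes, 11 of 13 hypertrophy genes and, downward, 8 of 16 ion channel genes passed, with adjusted p = 0.0163, 0.0237 and 0.0163 with an estimated correlation. Fatty acid oxidation then had 15 of 23 lower, the circadian clock 7 of 14 lower and 1 higher, calcium handling 4 of 16 and electron transport 4 of 27 lower, immediate-early genes 6 of 17 and inflammatory mediators 3 of 15 higher, with adjusted p of 0.191 to 0.400 with an estimated correlation. Cell type markers moved with them: endothelial (median 0.29, 2 of 11 passing upward, camera adjusted p = 0.0142), macrophage (0.39, 1 of 13 upward, camera adjusted p = 0.0173) and fibroblast (0.38, 4 of 11 upward and 1 downward, camera adjusted p = 0.0523), with adjusted p of 0.867 to 0.985 with an estimated correlation.

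In wild-type hearts no gene passed the test for banding, although the listed load-responsive genes lay mostly on the same side as in knockouts. Acta1 was 3008 ± 896 in sham and 6711 ± 1717 in banded hearts (SD, n = 3), a log2 difference of 1.17 (SE 0.36, adjusted p = 0.918). Myh7 was at 1.34 (SE 0.58, adjusted p = 0.921), Nppb at 1.02 (SE 0.45, adjusted p = 0.921), Nppa at 0.44 (adjusted p = 0.982) and Postn at 0.55. The smallest p-values belonged to Crim1, at 1.03 (SE 0.15, adjusted p = 0.138), and Resf1, at 1.37 (SE 0.21, adjusted p = 0.157), followed by the heat-shock gene Hspa1a (1.55), Sephs2 (-0.53) and Snrpd3 (-0.56). Limma called 0 genes, and 534 had an unadjusted p under 0.05. Individual wild-type arrays overlapped between the groups for Myh7: wild-type sham 1 read 5182 against 1109 and 1361 in the other shams, and wild-type banded 3 read 1918 against 10045 and 6718 in the other banded hearts.

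Several lists passed camera in wild-type hearts, each with 0 members passing and 0 adjusted over the list alone. Immediate-early genes had a median of 0.75 over 17 members (camera adjusted p = 4.9e-08; adjusted p = 0.519 with an estimated correlation), with Fos at 1.63 and Egr1 at 1.37. The extracellular matrix had a median of 0.32 over 34 members (camera adjusted p = 4.1e-06; adjusted p = 0.724 with an estimated correlation), with Col14a1 at 0.69. The hypertrophy and fetal program had a median of 0.30 over 13 (camera adjusted p = 4.3e-04; adjusted p = 0.519 with an estimated correlation). Inflammatory mediators were at 0.32 over 15 (camera adjusted p = 0.00104; adjusted p = 0.519 with an estimated correlation), with Cxcl1 at 0.66. The interferon response was at 0.17 over 17 (camera adjusted p = 0.00108; adjusted p = 0.724 with an estimated correlation), with Igtp at 0.72, and the unfolded protein response at 0.17 over 17 (camera adjusted p = 0.00342; adjusted p = 0.519 with an estimated correlation), with Asns at 0.53. Beside these groups, atrial markers had a median of 0.50 (camera adjusted p = 0.0202; adjusted p = 0.438 with an estimated correlation) and fibroblast markers of 0.25 (camera adjusted p = 0.00413; adjusted p = 0.438 with an estimated correlation). The mean log2 value of the atrial list was 11, 10.2 and 6.93 in wild-type banded 1, 2 and 3. The neutrophil genes S100a8 and S100a9 read 877 and 1041 in wild-type banded 2, and Xist, expressed from the inactive X chromosome of females, read 1255 in wild-type banded 3 alone. Without wild-type sham 1, 3 genes passed, Hoxa5 (1.89), Prxl2b (0.90) and Resf1 (1.57), and without wild-type sham 3, 10 lists passed instead of 6.

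**Figure D3:**
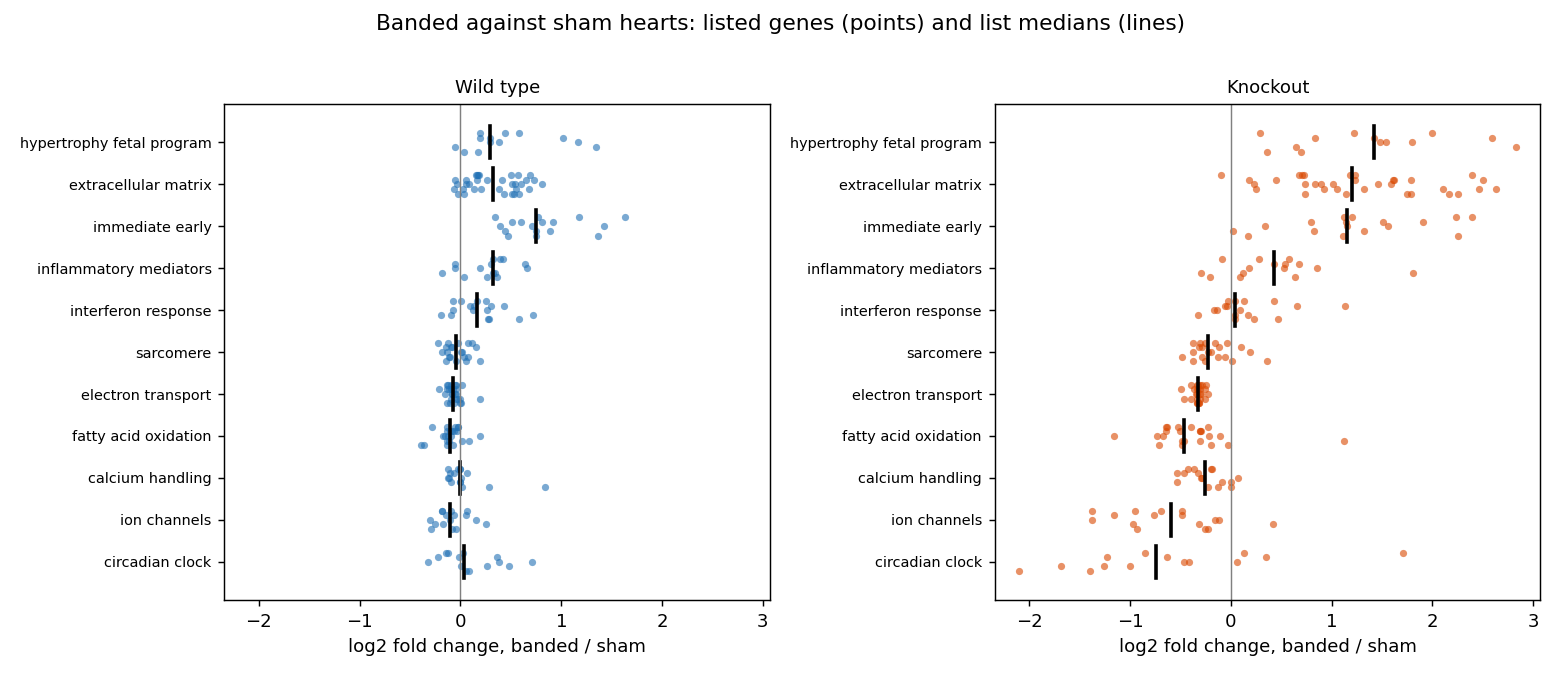
Log2 fold change of banded over sham (x axis) for the measured members of 11 gene lists (y axis), in wild type (left) and knockout (right), with each list's median as a line. The extracellular matrix median is 0.32 in wild type and 1.21 in knockout.

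Averaged over both genotypes, banding raised the load-responsive genes Abra, Acta1 and Myh7 and lowered the channel gene Kcnh2, in 6 against 6 arrays. Abra rose by 1.69 (SE 0.19, adjusted p = 0.00385), Resf1 by 1.39 (SE 0.15, adjusted p = 0.00385), Hspa1a by 1.47 (SE 0.21, adjusted p = 0.0133) and Acta1 by 1.35 (SE 0.26, adjusted p = 0.0295). Myh7 rose by 2.08 (SE 0.41, adjusted p = 0.0329). Ano10 fell by 1.43 (SE 0.22, adjusted p = 0.0164) and Kcnh2 by 0.84 (SE 0.12, adjusted p = 0.0133). In all 175 genes passed, 102 higher and 73 lower. Other named rises were Otud1 (1.49), Mfap5 (1.20), Maff (1.19), Hspa1b (1.18), Adamtsl2 (1.14) and the growth factor Hbegf (1.10). Other falls were Ift81 (-1.21), Adamts7 (-0.89), Emilin2 (-0.86), Gpr22 (-0.79), Car14 (-0.78), Rgs7bp (-0.76), Gm16793 (-0.74) and Smim5 (-0.71). Nppb (1.22, adjusted p = 0.0773) and Nppa (0.37, adjusted p = 0.606) did not pass.

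In the average over genotypes 7 of 34 matrix genes rose, among them Col1a1 (0.84), Col3a1 (0.99), Bgn (0.82) and Tgfb2 (1.03), 27 did not pass, and 27 were higher adjusted over the list alone (median 0.82, camera adjusted p = 4.1e-20; adjusted p = 0.281 with an estimated correlation). In the hypertrophy and fetal program 4 of 13 rose, Acta1, Myh7, Fhl1 (0.71) and Mybpc2 (1.29), 9 did not pass, and 10 were higher adjusted over the list alone (median 0.89, camera adjusted p = 1.1e-10; adjusted p = 0.239 with an estimated correlation). The mean log2 value of the matrix list was higher in banded hearts by 0.79 (exact p = 0.00649) and that of the hypertrophy list by 0.87 (exact p = 0.00433, 6 against 6 arrays). The ion channel list differed by -0.32 (exact p = 0.0130). By the same test exact p was 0.0693 for inflammatory mediators, 0.0758 for immediate-early genes and 0.0931 for electron transport. It was 0.121 for calcium handling, 0.156 for fatty acid oxidation and 0.310 for the interferon response. These p-values were not adjusted over the lists. Klf4 (0.69) was the 1 of 17 immediate-early genes that rose, 16 did not pass, and 4 were higher adjusted over the list alone (median 0.97, camera adjusted p = 1.7e-09; adjusted p = 0.333 with an estimated correlation). Of 16 ion channel genes 1 fell, Kcnh2, 15 did not pass, and 7 were lower adjusted over the list alone (median -0.36, camera adjusted p = 4.7e-05; adjusted p = 0.281 with an estimated correlation). Inflammatory mediators (median 0.34, camera adjusted p = 2.5e-04; adjusted p = 0.333 with an estimated correlation), the interferon response (0.15, camera adjusted p = 0.00979; adjusted p = 0.489 with an estimated correlation) and electron transport (-0.19, camera adjusted p = 6.0e-07; adjusted p = 0.480 with an estimated correlation) had 0 members passing and 0 adjusted over the list alone. Fatty acid oxidation (-0.27, camera adjusted p = 2.1e-06; adjusted p = 0.398 with an estimated correlation) and calcium handling (-0.12, camera adjusted p = 0.0373; adjusted p = 0.333 with an estimated correlation) had 0 members passing, and 3 and 2 lower adjusted over the list alone. Fibroblast markers had a median of 0.30 (camera adjusted p = 0.0358; adjusted p = 0.683 with an estimated correlation).

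The averaged count was 996 (476 higher, 520 lower) without the array labelled knockout banded 1, with all 175 genes shared, and 928 without that array and wild-type banded 3. It was 19 and 15 without knockout banded 2 and 3, 41, 8 and 5 without knockout sham 1, 2 and 3, 24, 21 and 108 without wild-type banded 1, 2 and 3, and 18 and 41 without wild-type sham 2 and 3. With the array labelled knockout banded 1 left out, 29 of 34 matrix and 10 of 13 hypertrophy genes rose and 7 of 16 ion channel genes fell (adjusted p = 0.0175, 0.0191 and 0.0191 with an estimated correlation). In that fit 7 of 17 immediate-early genes and 5 of 15 inflammatory mediators rose and 11 of 23 fatty acid oxidation, 3 of 14 clock and 2 of 16 calcium handling genes fell (adjusted p of 0.136 to 0.38 with an estimated correlation), with 4 of 11 fibroblast markers higher and 1 lower and 1 of 13 macrophage markers higher (camera adjusted p = 0.00790 for each; adjusted p = 0.631 with an estimated correlation).

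**Figure D4:**
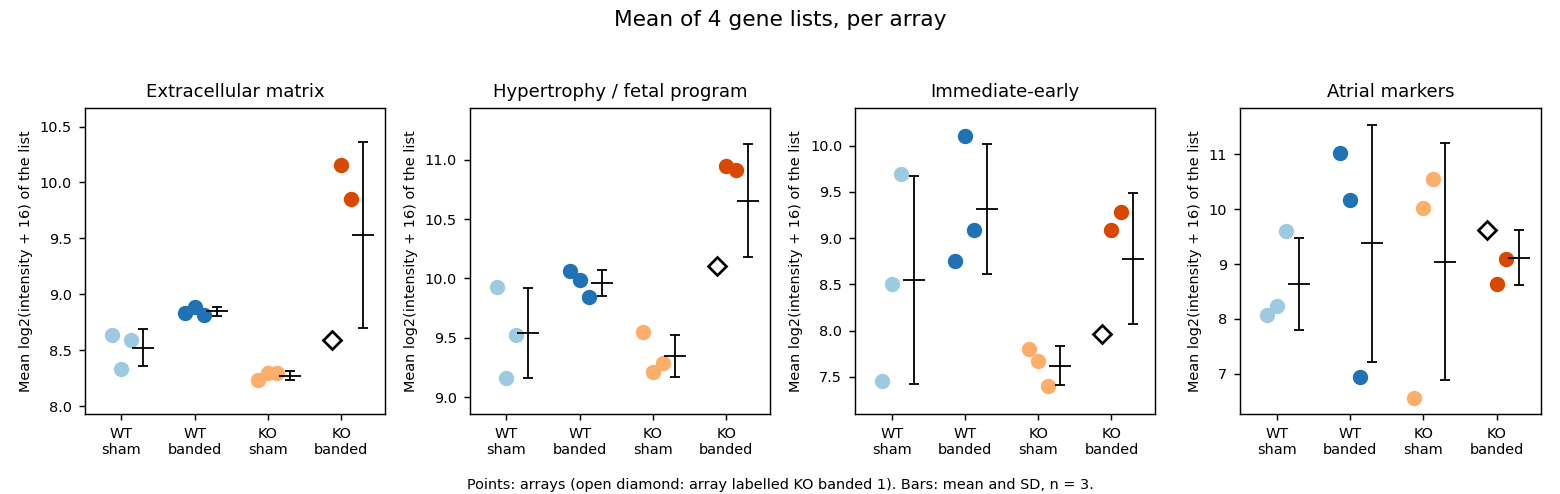
Mean log2(intensity + 16) of 4 gene lists per array (y axis) by group (x axis), with the mean and SD of 3 arrays beside each group. The matrix mean is 10.2 and 9.85 in knockout banded 2 and 3 and 8.59 in the array labelled knockout banded 1 (open diamond), and the atrial mean spans 6.57 to 11 over the 12 arrays.

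Whether the banding response differed between the genotypes was tested by the interaction. The matrix and hypertrophy lists had larger responses in knockout than in wild-type hearts by camera at the preset correlation, and the channel and metabolic lists had more negative ones, but none passed with an estimated correlation (adjusted p of 0.236 to 0.492) or by fry. The mean log2 value of the matrix list was 8.59 in the array labelled knockout banded 1. It was 10.2 and 9.85 in knockout banded 2 and 3, and 8.81 to 8.89 in the wild-type banded arrays. No single gene passed, with the smallest adjusted p at 0.274 for Ccdc141 (-0.97, SE 0.16), followed by Lrtm1 (-0.92), Fitm1 (-1.04), Crim1 (-1.14) and the splicing kinase Clk2 (-0.68). Limma called 0 genes, and 994 had an unadjusted p under 0.05. Postn was at 2.07 (SE 0.77, adjusted p = 0.48), Myh7 at 1.49 (SE 0.81, adjusted p = 0.60) and Apln at 1.23 (adjusted p = 0.442).

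Each of the 7 lists past camera for the interaction had 0 members passing. The extracellular matrix had a median difference of 0.87 over 34 genes, 1 higher adjusted over the list alone (camera adjusted p = 2.14e-10; adjusted p = 0.391 with an estimated correlation). The hypertrophy and fetal program was at 0.70 over 13, 1 higher adjusted over the list alone (camera adjusted p = 2.01e-05; adjusted p = 0.383 with an estimated correlation). Ion channels were at -0.53 over 16, 1 lower adjusted over the list alone (camera adjusted p = 1.16e-05; adjusted p = 0.236 with an estimated correlation), and calcium handling at -0.25 over 16, 1 lower adjusted over the list alone (camera adjusted p = 0.000138; adjusted p = 0.236 with an estimated correlation). Electron transport was at -0.24 over 27, 1 lower adjusted over the list alone (camera adjusted p = 3.88e-06; adjusted p = 0.492 with an estimated correlation). Fatty acid oxidation was at -0.36 over 23 (camera adjusted p = 7.09e-05; adjusted p = 0.492 with an estimated correlation) and the circadian clock at -1.0 over 14 (camera adjusted p = 0.00574; adjusted p = 0.391 with an estimated correlation), each with 0 adjusted over the list alone. Endothelial markers were at 0.28 (camera adjusted p = 0.0164; adjusted p = 0.975 with an estimated correlation).

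Without the array labelled knockout banded 1, chosen for removal after its Apln level was seen, 208 genes passed the interaction, 113 higher and 95 lower, and 96 without that array and wild-type banded 3. Knockout banded 2 and 3 are then the whole knockout banded group. The array left out responded less to banding than these, so its removal by itself enlarges the knockout response. Postn was then at 2.98 (SE 0.26, adjusted p = 5.5e-04), the cross-linking enzyme gene Lox at 2.65 (adjusted p = 3.4e-04), Nmrk2 at 3.16, Ltbp2 at 2.92, Cilp at 2.62, Thbs1 at 2.55, Ccn2 at 2.39, Col8a1 at 2.33 and elastin, Eln, at 2.30. The largest negative values were those of Ces1d (-2.45), Gdap10 (-2.35), the clock gene Per3 (-1.95), Mylk4 (-1.68), Kcnj5 (-1.56) and Nr1d2 (-1.46). In this fit 20 of 34 matrix genes passed upward (median 1.30, adjusted p = 0.0158 with an estimated correlation) and 2 of 16 ion channel genes downward (adjusted p = 0.0158 with an estimated correlation). The hypertrophy and fetal program had 6 of 13 higher (adjusted p = 0.0546 with an estimated correlation), fatty acid oxidation 5 of 23 lower (adjusted p = 0.20 with an estimated correlation) and the clock 2 of 14 lower (adjusted p = 0.204 with an estimated correlation). All 11 endothelial markers were positive too (median 0.34, 0 passing, 3 higher adjusted over the list alone, camera adjusted p = 0.00567; adjusted p = 0.678 with an estimated correlation), while fibroblast (0.02) and macrophage (0.31) markers did not pass camera.

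Of the 416 genes called for banding in knockout, 345 (82.9%) had the same sign in wild type. Their median change in the knockout direction was 0.76 in knockout and 0.17 in wild type, a comparison that favours the knockout because the genes were selected there. Across all tested genes the 2 sets of fold changes correlated at Pearson r 0.35 and Spearman rho 0.26, where genes are not independent replicates. Only the interaction tests whether the responses differ.

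Between banded hearts of the 2 genotypes no gene passed with all arrays, and the smallest adjusted p was 0.0755. It was shared by Pcp4l1 (-1.26, SE 0.19), Lima1 (-0.71, SE 0.11), Dlc1 (-0.78, SE 0.12), the hypertrophy-list gene Fhl1 (1.14, SE 0.18) and Mpv17 (-0.95, SE 0.15). Fhl1, a muscle LIM protein gene, read 6103 ± 1543 in knockout banded hearts (SD, n = 3). Postn was at 1.86 (adjusted p = 0.172), Nmrk2 at 2.21 (adjusted p = 0.141) and the lipid-metabolism regulator Ppara at -0.78 (adjusted p = 0.140). Limma called 0 genes, and 1594 had an unadjusted p under 0.05.

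The lists past camera between banded hearts, each with 0 members passing, again set matrix and hypertrophy genes against metabolic and channel genes at the preset correlation, and none passed with an estimated one. The extracellular matrix was at 0.58, 1 of 34 higher adjusted over the list alone (camera adjusted p = 8.5e-08; adjusted p = 0.50 with an estimated correlation), and the hypertrophy and fetal program at 0.63, 6 of 13 higher adjusted over the list alone (camera adjusted p = 6.2e-05; adjusted p = 0.355 with an estimated correlation). The mean log2 value of the matrix list was higher in knockout banded hearts by 0.69 (exact p = 0.40). That of the hypertrophy list was higher by 0.69 (exact p = 0.10, the smallest that 3 against 3 arrays can give). Electron transport was at -0.29, 1 of 27 lower adjusted over the list alone (camera adjusted p = 8.8e-09; adjusted p = 0.493 with an estimated correlation), with Uqcrc2 at -0.48. Fatty acid oxidation was at -0.34, 3 of 23 lower adjusted over the list alone (camera adjusted p = 8.2e-08; adjusted p = 0.392 with an estimated correlation), with Acaa2 at -0.95. Ion channels were at -0.32, 1 of 16 lower adjusted over the list alone (camera adjusted p = 1.6e-05; adjusted p = 0.354 with an estimated correlation), with Kcnh2 at -0.66. The unfolded protein response (-0.19, camera adjusted p = 0.00163; adjusted p = 0.355 with an estimated correlation) and the interferon response (-0.21, camera adjusted p = 0.00593; adjusted p = 0.663 with an estimated correlation) each had 2 of 17 lower adjusted over the list alone, with Igtp at -1.23 and Xbp1 at -0.40. Calcium handling (-0.21, camera adjusted p = 0.00311; adjusted p = 0.354 with an estimated correlation), the sarcomere (-0.18, camera adjusted p = 0.00900; adjusted p = 0.663 with an estimated correlation) and immediate-early genes (-0.49, camera adjusted p = 0.0114; adjusted p = 0.663 with an estimated correlation) had 0 adjusted over the list alone. The Actb 3' to 5' ratio was -0.20 ± 0.0231 in knockout and 0.15 ± 0.109 in wild-type banded arrays (SD, n = 3; exact p = 0.10).

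This comparison too depended on the array labelled knockout banded 1: without it 667 genes passed, 352 higher and 315 lower, and 354 without that array and wild-type banded 3. The knockout banded group is then knockout banded 2 and 3 alone, which responded more to banding. Nmrk2, a nicotinamide riboside kinase gene, was then higher in knockout by 3.07 (SE 0.31, adjusted p = 5.8e-04) and Postn by 2.77 (SE 0.20, adjusted p = 4.8e-05). Also higher were Ltbp2 (2.99), Cilp (2.65), Comp (2.36), Lox (2.24), Itgbl1 (2.22), Thbs4 (2.20), Col8a1 (2.16) and Meox1 (1.84). Lower were Tmprss13 (-2.77), Ces1d (-2.63), BC023105 (-2.62), Rgs2 (-2.06), Fbp2 (-1.97), Acot1 (-1.90), Phkg1 (-1.80) and Ttll1 (-1.70). In this fit 23 of 34 matrix genes were higher (adjusted p = 0.0256 with an estimated correlation), 6 of 13 hypertrophy genes higher (adjusted p = 0.0748 with an estimated correlation), 5 of 16 ion channel genes lower (adjusted p = 0.0256 with an estimated correlation) and 11 of 23 fatty acid oxidation genes lower (adjusted p = 0.129 with an estimated correlation). Without wild-type sham 1, 1 gene passed, Pcp4l1 (-1.26).

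In sham hearts no gene passed between the genotypes, and the smallest p was that of Apln, at -1.57 (SE 0.25, adjusted p = 0.401). The next smallest p-values were those of Pdzrn3 (-0.77, SE 0.14, adjusted p = 0.829), Coq10b (0.69), Amotl2 (-0.60) and Mov10l1 (0.61). Limma called 0 genes, and 570 had an unadjusted p under 0.05. Without the array labelled knockout banded 1, which enters only through the shared estimate of spread, Apln was the 1 gene called, at the same -1.57. That array was singled out by its Apln value, so the call follows from the choice.

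By list, immediate-early genes between sham hearts had a median of -0.94 over 17 members, 0 passing and 1 lower adjusted over the list alone (camera adjusted p = 9.1e-06; adjusted p = 0.687 with an estimated correlation). Their mean log2 value was 7.45, 8.50 and 9.70 in wild-type sham 1, 2 and 3, and 7.80, 7.67 and 7.40 in knockout sham 1, 2 and 3 (exact p = 0.30). Egr1 was at -2.10 and Ier2 at -1.35. The extracellular matrix was at -0.22 over 34 (camera adjusted p = 0.00145; adjusted p = 0.743 with an estimated correlation), with Thbs1 at -1.34, Mmp14 at -0.64 and Col3a1 at -0.61, and the interferon response at -0.18 over 17 (camera adjusted p = 0.0119; adjusted p = 0.743 with an estimated correlation), with Bst2 at -0.62, both with 0 passing and 0 adjusted over the list alone. Apelin, angiotensin and adrenergic genes were at -0.12 over 10, 0 passing and 1 lower adjusted over the list alone (camera adjusted p = 0.0113; adjusted p = 0.236 with an estimated correlation). Apln, the targeted gene, belongs to this list, so part of the list's fall follows from the knockout itself. The list was not tested without Apln. Among its other members Nos3 was at -0.33 and Corin at -0.26. Clock genes were at 0.57 over 14, with 0 passing and 0 adjusted over the list alone (camera adjusted p = 0.0109; adjusted p = 0.666 with an estimated correlation), Dbp at 1.61 and Per2 at 1.43. Smooth muscle and pericyte markers (-0.34, camera adjusted p = 1.6e-04; adjusted p = 0.0947 with an estimated correlation) and endothelial markers (-0.19, camera adjusted p = 1.6e-04; adjusted p = 0.226 with an estimated correlation) moved with these groups. The number of lists past camera was 5 with all arrays, 1 without wild-type sham 1, 8 without wild-type sham 2 or 3, and 2 without knockout sham 2.

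Averaged over surgery, no gene passed between the genotypes with all 12 arrays and 1 probe set per gene, while Rgs5 (-0.75), Cd99l2 (-0.70) and Fundc2 (-0.65) passed with the mean of a gene's probe sets. With 1 probe set per gene limma called 0 genes, 1158 had an unadjusted p under 0.05, and the smallest adjusted p was 0.237, that of Apln (-0.96, SE 0.18). Without the array labelled knockout banded 1, which leaves knockout banded 2 and 3 in that group, 141 genes passed, 80 higher and 61 lower, and 83 without that array and wild-type banded 3. Apln, by which that array was chosen, was then at -1.10 and among those called, which follows from the choice. Pdk4, a kinase that restrains glucose oxidation, was at -1.12, with the carbonic anhydrase gene Car4 (-0.65), the leucine-catabolism gene Ivd (-0.71), Scara5 (-0.86), Gcnt1 (-1.10) and Mvk (-1.07). Lrp11 (1.0), E230013L22Rik (0.96) and the amino acid transporter gene Slc7a5 (0.93) were higher.

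The lists past camera for genotype averaged over surgery had 0 members passing with all arrays. Fatty acid oxidation (median -0.20, camera adjusted p = 2.8e-06; adjusted p = 0.532 with an estimated correlation), electron transport (-0.17, camera adjusted p = 2.8e-06; adjusted p = 0.543 with an estimated correlation), ion channels (-0.14, camera adjusted p = 0.0160; adjusted p = 0.532 with an estimated correlation) and the sarcomere (-0.10, camera adjusted p = 0.0273; adjusted p = 0.812 with an estimated correlation) were lower in knockouts with 0 adjusted over the list alone. Immediate-early genes (-0.77, camera adjusted p = 5.2e-06; adjusted p = 0.532 with an estimated correlation), the interferon response (-0.15, camera adjusted p = 2.0e-04; adjusted p = 0.532 with an estimated correlation) and the unfolded protein response (-0.15, camera adjusted p = 9.5e-04; adjusted p = 0.532 with an estimated correlation) had 1, 1 and 3 members lower adjusted over the list alone. The hypertrophy and fetal program (0.18, camera adjusted p = 0.0194; adjusted p = 0.543 with an estimated correlation) had 1 higher adjusted over the list alone and the extracellular matrix (0.15, camera adjusted p = 0.0296; adjusted p = 0.812 with an estimated correlation) 0. Fibroblast markers were at -0.12 (camera adjusted p = 0.0313; adjusted p = 0.647 with an estimated correlation) and smooth muscle and pericyte markers at -0.24 (camera adjusted p = 0.00810; adjusted p = 0.292 with an estimated correlation). Leaving out the array labelled knockout banded 1, 8 of 34 matrix and 5 of 13 hypertrophy genes were higher and 5 of 23 fatty acid oxidation genes lower (adjusted p = 0.112, 0.146 and 0.146 with an estimated correlation). The number of lists past camera was 9 with all arrays and 5 without knockout banded 2.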

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

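The list tests, the fits that leave out 1 array at a time, the score of genotype built from sham arrays and the regroupings of arrays were chosen before their results were seen. The other tests here, and the use of those fits to weigh an explanation, were chosen after.

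Of the results picked out for a closer look, 7 are lists whose banding response differed between the genotypes by camera: extracellular matrix (adjusted p = 2.14e-10), electron transport (adjusted p = 3.88e-06), ion channels (adjusted p = 1.16e-05), hypertrophy and fetal program (adjusted p = 2.01e-05), fatty acid oxidation (adjusted p = 7.09e-05), calcium handling (adjusted p = 0.000138) and circadian clock (adjusted p = 0.00574). With an estimated correlation limma's camera called 0 of them (adjusted p of 0.236 to 0.492). Without the 3 genes shared with the fibroblast list, the matrix median was 0.94 for the interaction and 1.23 for banding in knockout. The others are probe sets with several genes or none listed, outside the main comparisons. Of 6055 tested, 2 passed for banding in wild type, 4 for genotype in banded hearts and 1 for banding averaged over genotypes, all lower. Without the array labelled knockout banded 1 these were 2, 67 and 59, with 135 for banding in knockout, 4 for the interaction and 7 for genotype averaged, each from 0.

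The array labelled knockout banded 1 has Apln at the wild-type level. An exchange with a wild-type array of the series is argued against, since the lowest wild-type Apln value was 1.279 times the highest of the other 5 knockouts, so no partner is out of place. A heart of the same background as the 6 wild-type arrays is argued against by the 10 genes whose probe sets best separated the genotypes in the other 11 arrays: the array's median position was 0.797 between the wild-type mean at 0 and the knockout mean at 1, with 8 of 10 on the knockout side, against 1 to 4 for wild-type arrays and 7 to 9 for the other knockouts. A wild-type animal bred within the knockout line stays open, because the score from sham arrays, 0.1605 above the wild-type banded mean, did not separate knockout banded 2 and 3 from wild type and decides nothing. Airway or fat tissue in the sample may also have added Apln, as Scgb1a1 was 21.94 times its level in the next highest array, but the Apln level of such tissue was not measured and wild-type banded 1, with Adipoq at 327 against 392 here, had the lowest wild-type Apln (205), so the explanations that remain cannot be told apart.

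The same array responded less to banding than knockout banded 2 and 3. The banding score used here was built from the genes called for banding in knockout, which these arrays helped to choose. On it this array was at 0.77 against 1.73 and 1.72. Dilution by airway or fat tissue as the whole cause is argued against, because its matrix genes lay at a median of -1.279 log2 from the other knockout banded arrays while its sarcomere genes lay at -0.0011. RNA quality is argued against too, since its Actb 3' to 5' log2 ratio differed from theirs by -0.00207. Among load genes, Myh7 was nearly alike in this array and in knockout banded 2 and 3, while the hypertrophy and fetal program lay at a median of -0.71 from theirs. The Myh7 values were close to the highest of any probe set in these arrays, 10813 to 11291. A limit of the signal could hide a difference there, so the likeness does not show an equal response. A milder banding or the presence of Apln could each be a candidate explanation, and neither was tested.

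No gene passed for banding in wild type. Adding the atrial score to the fit gave 0 genes, with 344 in knockout, and exchanging the labels of wild-type sham 1 and wild-type banded 3 gave 1, which argues against varying atrial content and against such an exchange as the whole cause. Whether these arrays carry each other's label cannot be told apart from a weak response by their scores: the banding scores, 0.20 and 0.25, differed by 0.05404, against a within-group SD of 0.150. The exchange gave 253 genes for banding averaged over genotypes, against the real 175, so an exchange as part of the cause stays open. Leaving out wild-type banded 3, the only array with Xist (1255), gave 0 genes, which decides nothing about the female array, as leaving out a knockout sham array cut 416 genes to 9, 40 or 88. A weak or uneven response to banding in these wild-type hearts stays open and was not tested.

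Regroupings of the arrays were counted that gave as many genes as the real groups. For banding averaged over genotypes 2 of 100 regroupings, the real one among them, gave as many genes as the real 175. That is a small share, and it does not exclude chance. The highest other count was 253, reached by exchanging wild-type sham 1 and wild-type banded 3. For the interaction and for genotype averaged over surgery the real count was 0, which all 100 of 100 regroupings reach by definition, so these regroupings test nothing there. The highest other counts were 1 for the interaction and 2 for genotype averaged. For the comparisons of 3 with 3 arrays there are 10 regroupings, too few for a share under 0.05. As many genes as the real count were given by 1 of 10 for banding in knockout (real 416, highest other 4) and, with real counts of 0 that every regrouping reaches, by 10 of 10 for banding in wild type (real 0, highest other 1), 10 of 10 for genotype in sham (real 0, highest other 0) and 10 of 10 for genotype in banded hearts (real 0, highest other 1).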

How the results depend on the processing

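No named gene that passed limma's test, and not Apln, changed direction under any setting, and directions of lists were not followed across settings. With all single-gene probe sets a named gene was still followed by its probe set of highest mean. That setting could therefore not show a reversal between probe sets, such as Nup62 at 0.35 against -1.60 for banding in knockout. Of the values of named genes under the settings that keep all arrays or leave out a pair, 1373 stayed on their side of the threshold, 104 lost the call and 21 gained it, and leaving out 1 array at a time 1008 stayed, 364 lost it and 20 gained it. Those that stayed include values that had not passed with all arrays. Of the 62 that had passed, 0 lost the call without the array labelled knockout banded 1, 51 without knockout banded 2 and 54 without knockout sham 3. Signal over background limits the weak genes: 25.8 to 29.8% of probe sets lay below 16, where the pseudocount shrinks ratios. In 10 of 119 pairs of list and contrast the median, mean and camera direction differed in sign, 0 of them past the threshold. Apln has 1 probe set, so testing each of its probe sets apart gave no other value. The fits without the array labelled knockout banded 1 and wild-type banded 3 (the pair) and with the atrial covariate were chosen after seeing the data. For every change below, the cause was not tested.

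The count for banding in knockout (416) was 212 without the filter, 1870 with array weights, 74 in a fit of only the groups compared, 237 with the replicate block and 1349 without the pair of arrays, and 9 to 1441 leaving out 1 array. That for banding averaged (175) was 77 without the filter, 88 without the variance trend, 769 with array weights, 60 with the replicate block and 928 without the pair, and 5 to 996 leaving out 1 array. Counts of 0 became, for genotype in sham, 1 with all single-gene probe sets (Prune2), and 0 to 1 leaving out 1 array. For genotype in banded hearts they became 581 with array weights, 1 with the mean of probe sets (Rgs5), 2 with all probe sets (Rgs5 and Cd99l2), 1 with the replicate block (Pcp4l1) and 354 without the pair, and 0 to 667 leaving out 1 array. For the interaction they became 1 with all probe sets (Prune2) and 96 without the pair, and 0 to 208 leaving out 1 array. For genotype averaged they became 3 with the mean of probe sets (Rgs5, Cd99l2 and Fundc2), 5 with all probe sets and 83 without the pair, and 0 to 141 leaving out 1 array. For banding in wild type the range was 0 to 3. Apln, knockout against wild type, ranged from -1.17 to -0.80.

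The replicate numbers share only a number: over 18 pairs of arrays with the same number, residual correlations had a median of -0.018, from -0.281 to 0.233, and 2 of 12 arrays matched their own number best. Of the lists past camera, in the order banding in wild type (6), in knockout (9), genotype in sham (5), in banded (10), interaction (7), banding averaged (9) and genotype averaged (9), an estimated correlation left 0 in all 7 and fry gave 0, 5, 1, 0, 0, 2 and 0. Without the filter genotype in sham gave 3, and without the pair genotype in banded gave 6. Leaving out 1 array the ranges were 5 to 10, 8 to 12, 1 to 8, 7 to 10, 6 to 10, 8 to 11 and 5 to 8.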

Other observations

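The tests in this part were chosen after the values were seen, except the share of Apln's neighbours and the correlation of Nppa with the atrial score. Smooth muscle and pericyte markers were mostly lower in sham knockout than in sham wild-type hearts. Of 7 measured genes 5 had negative and 2 positive values, 0 passed and 4 were lower adjusted over the list alone, with Myh11, the smooth muscle myosin, at -0.60, Tagln at -0.52 and Mylk at -0.45 (camera adjusted p = 1.6e-04; adjusted p = 0.0947 with an estimated correlation). Of 11 endothelial markers 0 passed and 2 were lower adjusted over the list alone, with the tight-junction gene Cldn5 at -0.87 and Pecam1 at -0.43 (camera adjusted p = 1.6e-04; adjusted p = 0.226 with an estimated correlation). The means of both lists were lower in all 3 sham knockouts than in all 3 sham wild types, by -0.17 and -0.23 log2 (exact p = 0.10 for each, the smallest that 3 against 3 arrays can give). Rgs5 is a member of the first list, but it entered the test by its probe set of highest mean and not by 1420940_x_at, which was lower in knockouts. With all 12 arrays the smallest camera adjusted p over the 7 contrasts was 0.0547 for mesothelium and epicardium, 0.0983 for adipocytes, 0.0986 for macrophages, 0.154 for nerve and glia, 0.194 for erythroid cells, 0.236 for neutrophils, 0.384 for sex-linked genes, 0.411 for mast cells and 0.697 for lymphocytes. Without the array labelled knockout banded 1, macrophages were at camera adjusted p = 0.0079 for banding averaged. Skeletal muscle and lung had fewer than 3 tested genes, with mean log2 values of 5.15 to 5.74 and 5.53 to 7.32 over the 12 arrays.

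Clock genes of opposite phase lay on opposite sides in sham hearts. Arntl, the positive limb of the clock, was at -1.59 in knockout against wild-type sham hearts while Dbp was at 1.61, Ciart at 1.74 and Per2 at 1.43, and with banding in knockout Arntl was at 1.71 while Dbp was at -2.10 and Ciart at -1.69. None of these passed with all arrays, and without the array labelled knockout banded 1 Arntl (2.33) and Dbp (-2.88) passed for banding in knockout. Dbp read 1187 to 1455 in the 3 knockout sham arrays and 911, 126 and 218 in the arrays labelled knockout banded 1, 2 and 3. The time of day at which the hearts were taken is not given in the sources used here. Immediate-early genes varied widely among wild-type sham arrays, with Fos at 40.6, 631 and 1644 and Egr1 at 220, 1690 and 4037 in arrays 1, 2 and 3, and less among knockout sham arrays, with Fos at 108, 70.5 and 38.8.

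A Prune2 probe set, 1432198_at, read 1696 ± 589 in knockout sham hearts, 97.6 ± 2.32 in knockout banded, 57.9 ± 33.7 in wild-type sham and 62.2 ± 17.9 in wild-type banded hearts (SD, n = 3). The probe set of highest mean for Prune2 was at -0.53 for genotype in sham (adjusted p = 0.930) and rose by 1.28 with banding in knockout (adjusted p = 0.0225). This gene was chosen after its values were seen.

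Apln, Cd99l2 and Fundc2 all lie on the X chromosome. Alleles carried along with the targeted gene may differ from those of the wild-type mice, and this was tested on the 40 measured genes nearest to Apln: 3 of them, 7.5%, had an unadjusted p under 0.05 for genotype averaged over surgery, against 10.6% of all tested genes, and limma called 0. The test used each gene's probe set of highest mean, by which Cd99l2 and Fundc2 themselves did not pass. It could therefore miss differences confined to other probe sets. The share differs from that of all genes by less than its counting error, so passenger alleles and their absence cannot be told apart in these data.

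Nppa, a natriuretic peptide gene also abundant in atria, differed little between banded and sham hearts, while atrial markers varied widely between arrays. The deviations of Nppa from the group means followed those of the atrial score at Pearson r 0.4837 over 12 arrays (permutation p = 0.0556; Spearman rho 0.441, permutation p = 0.203), and r was 0.413 without the 2 arrays farthest from the median. With the atrial score in the fit the averaged banding effect on Nppa was 0.28 (SE 0.31, adjusted p = 0.688), against 0.37 (SE 0.34) without it. Adjusting for the atrial score thus uncovered no change in Nppa with banding, and whether atrial tissue contributes to its level stays open at this correlation.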
